A study of Drosophila melanogaster with 36 samples.

How the data were processed

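RNA was measured in the fat body of third-instar Drosophila melanogaster larvae, the organ that stores lipid and glycogen and secretes most hemolymph proteins. Larvae of w1118, a common laboratory strain, and of per0, which lacks a functional period clock gene, were sampled in constant darkness at 9 time points from CT0 to CT32, every 4 h, with 2 libraries per genotype and time, 18 per genotype and 36 in all. Per the labels' protocols each library came from total RNA of 5 larvae of mixed sex and was made with SMART-Seq v4, a full-length cDNA kit that amplifies by PCR and keeps no strand or molecular identifier. CT is circadian time, the hour of the subjective day.

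The authors deposited a table of raw counts per gene for each genotype, with 17610 genes each. STAR 2.7.9a, featureCounts, edgeR and DESeq2 1.30.1 were used upstream, per the submitters' processing notes, which give no role or order. The genome build and annotation were not given in the sources used here. The authors also deposited a normalized table per genotype, a signal made of gene counts divided by a size factor. In w1118 and per0, 99.8 and 99.9% of values lay within 1% of a single factor per library, and only genes well above the detection limit were listed (6138 for w1118 and 5930 for per0). These tables entered 1 alternative and no main result.

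Total counts per library ran from 16513757 to 28423768. A floor of 3 counts corresponded to 0.106 to 0.182 CPM, counts scaled to a common library size, and such floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Columns carry the letters A and B, which no label ties to the replicate numbers, so replicate numbers blocked no fit. The labels do not say whether duplicates came from separate cultures, and p-values may therefore measure only the spread between these pools. A w1118 CT0 sample carries a genotype tag naming per0, against its title and library name. It was kept as w1118.

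Gene counts were analysed with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values (TMM) scaling, filterByExpr by genotype and time group, and the quasi-likelihood F test. All adjusted p-values are from this test with Benjamini-Hochberg adjustment unless another tool is named, and a gene was called at an adjusted p under 0.05. Rhythms were fitted within each genotype with cosine and sine pairs of 24 h and 12 h together, and their size is the peak-to-trough difference in log2 with its standard error. Alternation with an 8 h period, the shortest that samples 4 h apart can carry, was added to that model. A factor of the 9 times tested any difference between times. CT24, CT28 and CT32 were compared with CT0, CT4 and CT8 with clock phase as a factor, called here the second day against the first. Genotypes were compared with time as a factor, and differences between genotypes in rhythm or in second-day change were tested as interactions. Lone samples left when a duplicate was omitted were assumed to vary like the other groups. CPM values shown were scaled by TMM over all 36 libraries.

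A set of 30 gene lists, 409 genes in all, was written before the data were examined, as were the designs, tests and most alternatives, and 405 genes matched. The lists were core clock, reported clock outputs, fatty acid synthesis, glycerolipid synthesis and lipid droplet, lipases, fatty acid oxidation, lipoproteins and lipid transport, glycolysis with glycogen and trehalose, insulin and nutrient response, antimicrobial peptides, larval serum proteins, ecdysone and juvenile hormone response, unfolded protein response, heat shock, oxidative stress and detoxification, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, mitochondrial respiratory chain, mitochondrial genome transcripts, strain markers, sex composition, and markers of hemocytes, midgut, salivary gland, muscle, neurons and glia, gonad, cuticle and epidermis, and Malpighian tubule. For direction tests lists were compared with other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. The rotation test fry asked whether a list shifted in one direction, without comparing it with other genes. The mean z-scored log2(CPM + 0.5) of each list was also tested for 24 h and 12 h pairs against all 362880 orders of the time points, an exact permutation test, with 120 tests adjusted together.

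Genes were named by a fixed rule. For rhythm, any-time and interaction results it took the 10 smallest p-values past the threshold among genes of at least 10 CPM, or the 5 smallest as not passing. For genotype and day results it took the 10 largest changes each way. Core clock genes, w, y and the roX genes were always eligible, as were up to 4 members per list with the smallest p. Some genes were named outside this rule after their values were seen, namely those that separate the genotypes in the mixed library described next, and genes named for one comparison whose values are also given for another. Antisense, overlapping and near-identical genes are uncertain because reads carry no strand.

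After the data were examined, each library was placed between the genotypes. Genes were chosen without the library in question, with the lowest decile in one genotype at least 2 CPM and over 2 times the highest decile of the other, and medians over 4 times apart. The share of the way from the library's own genotype to the other was computed per gene. The per0 CT28 library of column B lay between the genotypes. It stayed in the fits because the design was fixed before, and counts of called genes without it are printed beside those with it. Values of single genes, splits of the samples and some list counts include it unless stated.

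Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors in edgeR, no count filter, a filter of 10 CPM in 4 libraries, covariates, other periods, and the omission of each library or time. The steps were tested on simulated counts in which 200 genes had changed, all of at least 10 CPM. Simulated libraries were independent, with the spread taken from the duplicates. They held no differences between collections or in pool composition, so recovery in the real data may be lower. At a log2 difference of 2 the tests recovered 85% of changed genes for the 24 h rhythm in w1118, 87% in per0, 92% and 93% for the second day and 97% for genotype, but 36% and 22% for any time difference. At a log2 of 1 they recovered 15 to 38% for 24 h and 12 h rhythms and their differences.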

Results

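The study asked whether gene expression in the larval fat body, in particular of lipid metabolism, cycles over the day, and whether such cycles need the circadian clock. The 36 libraries comprised 18 from w1118 and 18 from per0. Totals ran from 16948806 to 25110769 counts in w1118 and from 16513757 to 28423768 in per0. Genes detected ran from 10771 to 13698 in w1118 and from 9472 to 12955 in per0.

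The per transcript, the target of the per0 mutation, was scarce, at or under 2.06 CPM in all libraries. In w1118 it measured 0.175 and 0.315 CPM at CT0, 0.239 and 0.269 at CT4, 0.579 and 0.158 at CT8, 0.166 and 0.109 at CT12, 0.0526 and 0 at CT16, 0.253 and 0 at CT20, 0.107 and 0.705 at CT24, 0.279 and 0.397 at CT28, and 1.2 and 0.286 at CT32. In per0 it measured 0.212 and 0.139 CPM at CT0, 0 and 0.223 at CT4, 0.202 and 0.538 at CT8, 0 and 0.168 at CT12, 0 and 0.242 at CT16, 0 and 0.225 at CT20, 0 and 0 at CT24, 0 and 2.06 at CT28, and 0 and 0.6 at CT32. The difference of -0.45 ± 0.72 log2 did not pass (adjusted p = 0.617), and per RNA therefore checks no genotype label here.

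One per0 library held expression of both genotypes. In the per0 CT28 library of column B, 20 genes higher in w1118 reached a median share of 0.52 of the way to their w1118 level, with quartiles of 0.3 and 0.7. Over the other 17 per0 libraries this median lay between -0.01 and 0.03. The nicotinic receptor subunit nAChRalpha7 measured 15.3 CPM there, against at most 1.08 in the other per0 libraries and a median of 36.1 in w1118. The heparan sulfotransferase Hs3st-A measured 19 CPM against at most 0.504, and mthl8 4.49 CPM against at most 0.403. The 25 genes higher in per0 lay a median share of 0.57 toward w1118 in it, against -0.32 to 0.27 in the other per0 libraries. In w1118 no library exceeded a median share of 0.01 over genes higher in per0, the CT0 libraries included, 1 of which carries the conflicting tag. Genes higher in w1118 lay a median share of 0.23 and 0.29 toward per0 in the CT0 libraries, against -0.37 to 0.37 over the other w1118 libraries. Of 200 genes that separated the genotypes at the other times, 123 and 118 lay nearer the w1118 mean in them, and 9 and 15 in the per0 CT0 libraries. Counts of called genes are given with and without per0 CT28 B, and other values include it unless stated.

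The first comparison asked which genes followed a 24 h rhythm in w1118. Most genes called had a fitted peak between CT10 and CT18, but 23 of 100 orders of the time points gave as many calls. The neuropeptide gene CNMa changed by 5.52 ± 0.46 log2 from peak to trough with a peak at CT14.6 (n = 18 libraries, adjusted p = 0.000302). Thor, the translation repressor 4E-BP that is induced on starvation, changed by 4.95 ± 0.51 log2 (adjusted p = 0.00105), and aay, a phosphoserine phosphatase, by 4.00 ± 0.40 log2 (adjusted p = 0.000541). Glutamine synthetase Gs1 changed by 2.90 ± 0.29, osi by 2.54 ± 0.23 and the transcription factor REPTOR-BP, which acts downstream of TOR, by 2.0 ± 0.22 log2. Thor ranged from 19.7 to 62.4 CPM at CT0, CT4, CT24 and CT28 and from 145 to 1050 CPM at the other times.

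In total 72 of 11650 genes passed for 24 h in w1118, of which 63 had a fitted peak between CT10 and CT18 and 9 between CT22 and CT6. The mean z-score of those 63 in w1118 was 1.05 at CT12, 0.91 at CT16 and 1.04 at CT20, a plateau. These phases were not sampled again on the second day, so a return of the peak was not observed. Voom called 72 and DESeq2 406, and edgeR called 40 with a roX covariate, 119 with gonad markers, 162 with the filter of 10 CPM and 183 with linear time. The 6 genes named above lost their calls with a 20 h pair alone, REPTOR-BP also with the 24 h pair alone, 4 of them with a 28 h pair alone and Thor without CT16, and kept them in the other alternatives. Thor and REPTOR-BP were the 2 members called of the 18 insulin and nutrient genes, and 5 passed adjusted over the list alone. No core clock gene passed, with 3.39 ± 1.07 log2 for per (adjusted p = 0.402), and none of the 16 fatty acid synthesis genes did. The lipid droplet gene Jabba measured 1.40 ± 0.29 log2 (adjusted p = 0.0847), and 1 of 20 glycerolipid genes passed adjusted over the list alone. Fatty acid oxidation had 2 of 23 such members, with Mfe2 at 0.67 ± 0.16 log2 (adjusted p = 0.17), and the unfolded protein response 7 of 19. The number of calls fell to 11 without w1118 CT16 B, to 19 without CT12 B, to 37 without CT4 B and to 41 without CT0 A, and to 13 without both CT12 libraries, 26 without CT4 and 33 without CT16. It rose to 137 without both CT0 libraries.

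**Figure D1:**
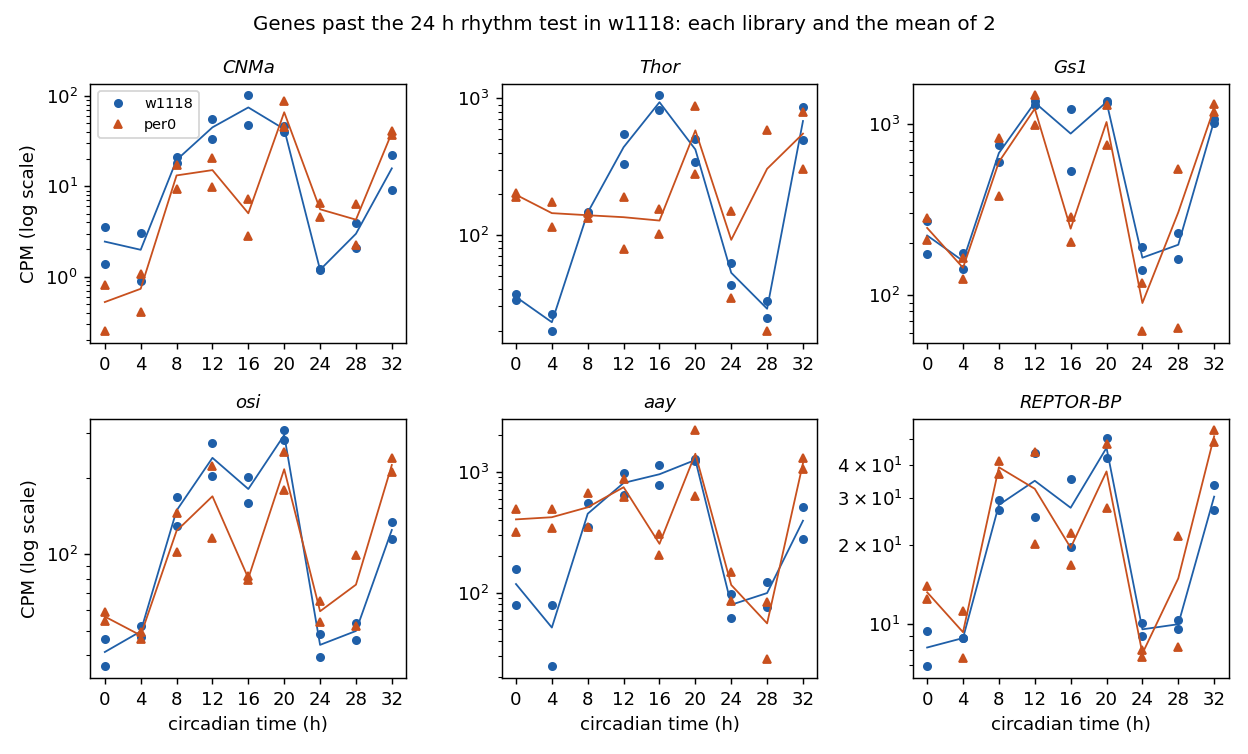
Expression in CPM on a log axis against circadian time in hours for CNMa, Thor, Gs1, osi, aay and REPTOR-BP, with each point 1 library, lines through the mean of 2 libraries, and colours for w1118 and per0. Thor in w1118 lay between 19.7 and 62.4 CPM at CT0, CT4, CT24 and CT28; the upper of the per0 points at CT28 for Thor, 590 CPM, is the library that held expression of both genotypes.

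Shorter periods in w1118 were tested next, since the study is about ultradian rhythms. No gene passed for 12 h in w1118 by edgeR, with 992 genes at an unadjusted p under 0.05 and 582 by chance. Voom called 0 and DESeq2 254. The smallest adjusted p was 0.0988, for CG8249 (2.37 ± 0.30 log2) and CG5321 (1.53 ± 0.21 log2). Of lipid genes, the triglyceride lipase bmm measured 2.27 ± 0.55 log2 and CG5966, also in the lipase list, 2.47 ± 0.61 log2 (adjusted p = 0.472 for each). In ribosome biogenesis 17 of 18 genes passed adjusted over the list alone, as did 15 of 19 unfolded protein response genes and 3 of 12 lipases, against 0 over all genes. Members that move together can pass together. Tested as single profiles, ribosome biogenesis and the unfolded protein response gave exact permutation p-values of 0.21 and 0.0324 for 12 h (adjusted p = 0.905 for each). Tif-IA, an initiation factor of RNA polymerase I, measured 0.60 ± 0.13 log2 and the ER chaperone Gp93 1.28 ± 0.27 log2 (adjusted p = 0.446 for each). Leaving out both w1118 CT0 libraries gave 448 calls, leaving out CT12 gave 4 and CT8 gave 1.

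No gene passed for 8 h alternation in w1118 by edgeR. There were 744 genes at an unadjusted p under 0.05, voom called 0 and DESeq2 7. In no list did a member pass adjusted over the list alone.

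The same tests were run in per0, and none of 10926 genes passed for 24 h by edgeR, with 1148 at an unadjusted p under 0.05, 0 by voom and 93 by DESeq2. The genes that led in w1118 measured 0.71 ± 0.83 log2 for Thor (adjusted p = 0.918), 1.90 ± 0.96 for CNMa (adjusted p = 0.595), 0.99 ± 0.36 for osi (adjusted p = 0.471), 1.27 ± 0.34 for REPTOR-BP (adjusted p = 0.464), 1.87 ± 0.67 for Gs1 (adjusted p = 0.471) and 0.91 ± 0.77 for aay (adjusted p = 0.854). These values include the mixed library, which held the higher Thor value of the CT28 duplicates, and CT28 was a low time for Thor in w1118. Ribosome biogenesis had 16 of 18 members passing adjusted over the list alone and 0 over all genes, with nop5 at 2.12 ± 0.45 and Nop60B at 1.90 ± 0.43 log2 (adjusted p = 0.453 for each). Tested as a single profile, that list gave an exact permutation p of 0.199 for 24 h (adjusted p = 0.905). Fatty acid oxidation had 4 of 23, the unfolded protein response 5 of 19 and heat shock 3 of 10. Without the mixed library these 4 lists had 16 of 18, 5 of 23, 5 of 19 and 2 of 12.

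For 12 h in per0 no gene passed by edgeR, with 10.2% of genes at an unadjusted p under 0.05, 0 by voom and 313 by DESeq2. Jabba measured 1.55 ± 0.28 log2 and REPTOR-BP 1.81 ± 0.33 log2 (adjusted p = 0.175 for each), and the adipokinetic hormone receptor AkhR, which triggers lipid release, 1.36 ± 0.33 log2 (adjusted p = 0.298). Adjusted over the list alone, 4 of 23 fatty acid oxidation genes and 4 of 18 nutrient genes passed, and 4 and 6 without the mixed library. Without the mixed per0 CT28 B library 1 gene passed, the cystathionine gamma-lyase gene Cth (1.49 log2, adjusted p = 0.0419), and the 24 h count stayed at 0. Without per0 CT8 A 26 genes passed, without CT24 B 3, and without both CT8 libraries 424.

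For 8 h alternation in per0, no gene passed by edgeR, with 595 at an unadjusted p under 0.05, 0 by voom and 40 by DESeq2, and none passed without the mixed library. Adjusted over the list alone 12 of 14 muscle markers passed, and 7 of 23 fatty acid oxidation genes, among them Mtpbeta at -0.37 ± 0.08 log2 (adjusted p = 0.494). Both list counts were the same without the mixed library. No list was tested as a single profile for 8 h, and members that move together can pass together.

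Whether rhythms differed between genotypes was tested directly. For 24 h no gene passed by edgeR, with 734 at an unadjusted p under 0.05, 0 by voom and 10 by DESeq2. Thor differed by 5.46 log2 with the mixed library included (adjusted p = 0.548). For 12 h no gene passed by edgeR, with 1730 at an unadjusted p under 0.05, 0 by voom and 4 by DESeq2, and pn differed by 1.48 log2 (adjusted p = 0.162). The loss of 24 h calls in per0 was thus not shown to be a difference between genotypes. Adjusted over the list alone, the 24 h difference passed for 14 of 19 unfolded protein response genes and 13 of 31 proteasome genes, and the 12 h difference for 22 of 31 proteasome genes. Without the mixed per0 CT28 B library these counts were 11, 11 and 8, and both counts over all genes stayed at 0. Members that move together can pass together, and no list was tested as a single profile for the difference. The list counts therefore do not show that these lists differed in rhythm.

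**Figure D2:**
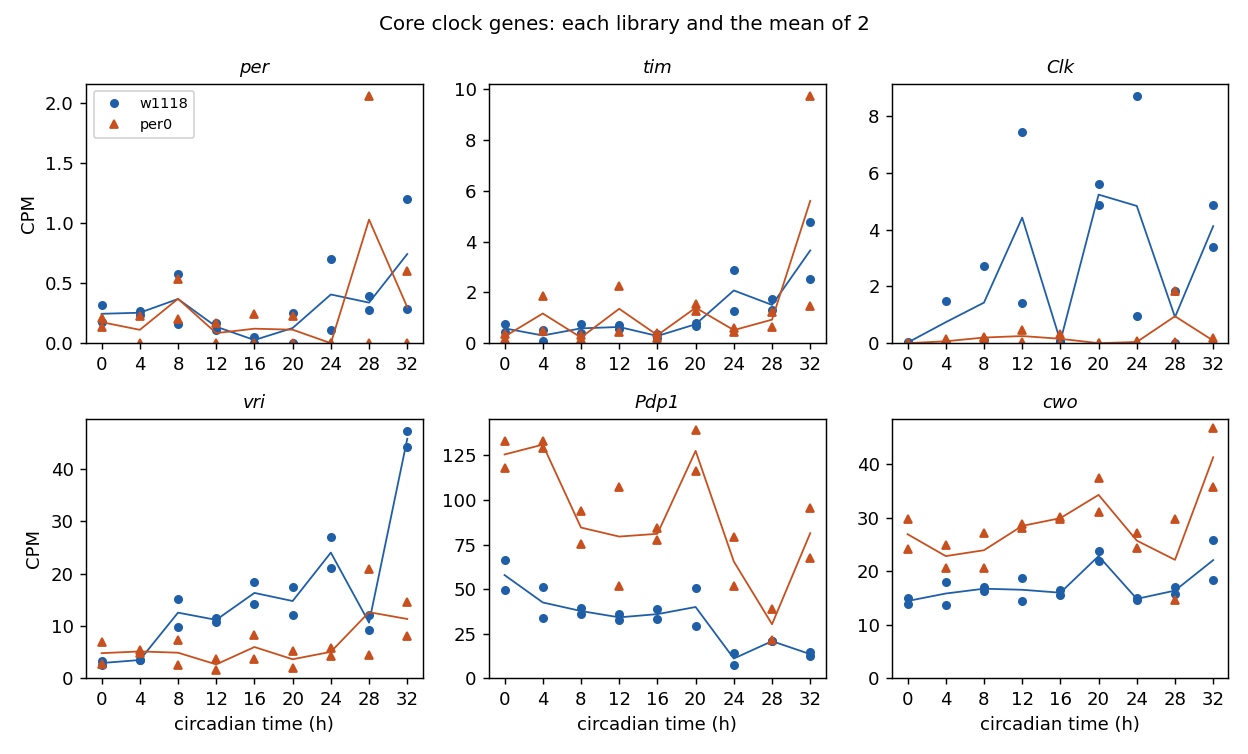
Expression in CPM, on linear axes from 0, against circadian time in hours for per, tim, Clk, vri, Pdp1 and cwo, with points for libraries and lines for the mean of 2 libraries in each genotype. Per stayed at or under 2.06 CPM in all libraries, and that highest value belongs to the per0 CT28 B library.

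Differences between any of the 9 times, of whatever shape, were called far more often than rhythms. The any-time test was judged by the spread of duplicates alone. The rhythm tests also took departures of times from the curve as error, so the counts are not on the same footing. In w1118 1426 of 11650 genes passed, led by Thor (range 5.35 log2, adjusted p = 0.000143), and including bmm at 3.59 and the clock gene vri at 3.95 log2 (adjusted p = 0.000615 for each). The respiratory chain had 49 of 65 members called (61 adjusted over the list alone), ribosome biogenesis 16 of 18 (18), glycolysis 16 of 25 (18) and fatty acid synthesis 11 of 16 (12). Fatty acid oxidation had 1 of 23 (0). In per0 1061 of 10926 genes passed, among them Cyp304a1 with a range of 5.83 log2 (adjusted p = 0.00151), and fatty acid oxidation had 10 of 23 called (18 adjusted over the list alone), nutrient genes 9 of 18 (9) and fatty acid synthesis 2 of 16 (7). The per0 count was 998 without the mixed CT28 B library, and 811 genes were called both times. Those 3 lists then had 10 (18), 7 (11) and 2 (11). It fell to 396 without per0 CT32 B, 426 without CT0 A, 484 without CT0 B, 530 without CT4 B, 546 without CT4 A and 632 without CT32 A, and to 410, 425 and 578 without both libraries of CT32, CT0 and CT4. The w1118 count fell to 841 without CT0 A, and was 884 with a roX covariate and 765 with a gonad marker covariate.

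Averaged over each list, no rhythm passed in either genotype. Over 30 lists, exact permutation tests gave a smallest adjusted p of 0.905 (9 time points). With linear time removed it was 0.108, and without per0 CT0 B it was 0.249, the lowest with a single library left out. Unadjusted exact p-values in w1118 were 0.989 for 24 h and 0.965 for 12 h in fatty acid synthesis, 0.78 and 0.429 in lipases, and 0.127 and 0.184 in fatty acid oxidation. The smallest in w1118 was 0.0324, for 12 h in the unfolded protein response, and in per0 0.00785, for 12 h in lipoproteins (exact permutation tests). Without the mixed library the smallest over lists in per0 was 0.0144, for 12 h.

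**Figure D3:**
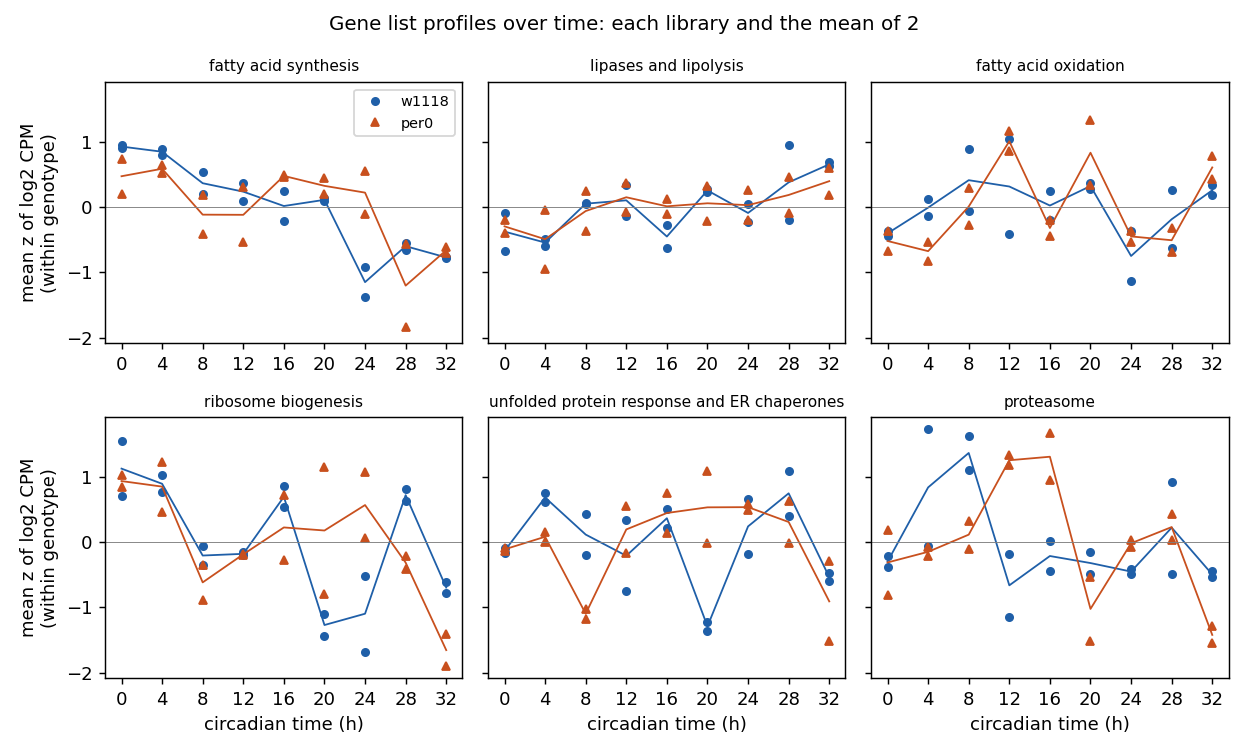
Mean z-scored log2 CPM of list members against circadian time in hours for fatty acid synthesis, lipases, fatty acid oxidation, ribosome biogenesis, unfolded protein response and proteasome, in w1118 and per0. None of these lists passed a 24 h or 12 h test, the smallest adjusted p over all lists being 0.905.

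Times a day apart share their clock phase, so the second day against the first shows change that is not a 24 h cycle. In w1118 most genes of the fatty acid synthesis, respiratory chain and ribosomal protein lists were called lower and most larval serum protein genes higher, although no list passed the camera test with an estimated correlation. By fry these 4 lists passed (adjusted p of 0.000196, 0.000355, 0.0049 and 0.00203). The pentose phosphate enzymes Zw and Pgd, sources of NADPH, changed by -2.28 ± 0.16 and -1.54 ± 0.10 log2 (n = 6 libraries against 6, adjusted p = 0.000537 for Pgd). Acly, which makes acetyl-CoA for lipid synthesis, changed by -1.98 ± 0.17 log2 and the lipogenic regulator SREBP by -0.76 ± 0.08 log2. The lipases Lip4 and bmm rose, by 1.49 ± 0.16 and 1.52 ± 0.30 log2. Of 28 called genes followed by name 16 lost their call when a library or phase was left out, bmm and Lsp2 among them, and 4 under another alternative.

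Of 11394 genes 1715 passed in w1118, 521 higher and 1194 lower on the second day, and 1013 with a gonad marker covariate. Fatty acid synthesis had 12 of 16 members lower and 0 higher (13 called adjusted over the list alone). The camera test passed at 3.41e-15, but gave adjusted p = 0.174 with an estimated correlation. Glycerolipid synthesis had 9 of 20 lower (9 adjusted over the list alone), with Jabba at -0.68 ± 0.11 log2, and lost its call (adjusted p = 0.229 with an estimated correlation). Lipases had 2 of 12 higher (3), fatty acid oxidation 2 higher and 6 lower of 23 (9), and lipoproteins 5 higher and 3 lower of 16 (9), among them the lipophorin receptor LpR1 at -1.79 ± 0.28 log2. Glycolysis had 13 of 25 lower (18), with pyruvate kinase Pyk at -2.36 ± 0.20 and Hex-C at -3.87 ± 0.51 log2 (adjusted p = 0.207 with an estimated correlation). The respiratory chain had 60 of 65 lower (60), with ND-30 at -1.06 ± 0.11 log2 (adjusted p = 0.207 with an estimated correlation). Ribosomal proteins had 74 of 90 lower (83), with RpLP2 at -0.79 ± 0.13 log2 (adjusted p = 0.451 with an estimated correlation). Larval serum proteins had 5 of 6 higher (5), with Lsp2 at 4.14 ± 0.98 and Lsp1alpha at 2.87 ± 0.65 log2 (adjusted p = 0.266 with an estimated correlation), and the ecdysone response 4 of 17 (4), with EcR at 1.21 ± 0.19 and Eip74EF at 1.58 ± 0.28 log2.

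Ribosome biogenesis had 2 of 18 lower (12 adjusted over the list alone, adjusted p = 0.619 with an estimated correlation), proteasome 5 of 31 (9, adjusted p = 0.705 with an estimated correlation), mitochondrial transcripts 5 of 17 (7, adjusted p = 0.619 with an estimated correlation), detoxification 5 higher and 5 lower of 23 (11), and nutrient genes 2 and 2 of 18 (5). Antimicrobial peptides had 1 of 18 higher (1), heat shock 1 of 9 lower, and the unfolded protein response 1 and 1 of 19. In the core clock vri, tim and cyc rose, by 2.15 ± 0.27, 2.21 ± 0.51 and 1.19 ± 0.35 log2, and Pdp1 and CkIIbeta fell, by 1.66 and 0.36 on the log2 scale. Clock outputs had 2 of 5 lower, with speck at -0.86 ± 0.20 log2. Among tissue markers, hemocytes had 1 higher and 5 lower of 12 (8), salivary gland 4 of 10 higher (6), cuticle 2 of 12 higher (5) and neurons 1 of 12 higher. None of 17 midgut (median -1.35 log2), 14 muscle or 5 Malpighian tubule markers passed, nor any of 5 sex composition or 3 strain genes. The gonad list had 0 of 23 called and a median of 2.32 log2 (camera adjusted p = 0.00126, adjusted p = 0.768 with an estimated correlation). The count of calls was 949 without w1118 CT0 A and 970 without CT0 B, and 557 and 699 without the phases of CT0 and CT8. With the filter of 10 CPM the share higher was 46% against 30.4%, and genes tested with and without that filter shifted by a median of 0.12 log2.

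In per0 the log2 rise of the storage proteins was larger. Lsp1 genes took 1.03 to 6.23% of counts in first-day per0 libraries, against 8.71 to 28.34% in w1118. On the second day they took 19.29 to 33.98% in per0 and 30.75 to 34.92% in w1118. For Lsp1 the larger rise thus came from a lower start and not from a higher final level. Lsp2 rose by 12.57 ± 1.20 log2 (adjusted p = 0.00046), Lsp1alpha by 8.23 ± 1.22 and Lsp1gamma by 4.69 ± 0.58 log2, and all 6 larval serum protein genes passed (6 adjusted over the list alone). Of 16 ecdysone response genes 6 were called higher and 1 lower (9 adjusted over the list alone, camera adjusted p = 0.46 with an estimated correlation), with Eip74EF at 3.50 ± 0.28, br at 2.94 ± 0.37 and EcR at 1.92 ± 0.25 log2. Of 14 cuticle genes 6 were called lower and 1 higher (7, camera adjusted p = 0.758 with an estimated correlation), with Ccp84Ag at -10.02 ± 1.52 log2. CG13068 measured -9.76 ± 0.94 log2. The male-expressed roX1 measured 87.5 to 341 CPM in the 6 first-day libraries, but 0.953 in CT24 B, 0.468 in CT28 A and 2.15 in CT32 A. It measured 145 CPM in CT24 A, 158 in CT32 B and 81.2 in the mixed CT28 B. The sex of some second-day pools thus differed from that of the first day. With roX genes as a covariate 1427 genes passed, Lsp2 among them.

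Of 10552 genes 1752 passed in per0, 946 higher and 806 lower. Without the mixed CT28 B library 2615 of 10924 passed, 1173 higher and 1442 lower, and 1606 were called both times. Nutrient genes had 6 of 18 higher (6 adjusted over the list alone), with foxo at 1.22 ± 0.19 and chico at 0.60 ± 0.09 log2 (adjusted p = 0.46 with an estimated correlation). The respiratory chain had 15 of 63 lower (52, adjusted p = 0.708 with an estimated correlation), fatty acid synthesis 3 of 16 lower (3), with Zw at -0.97 ± 0.26 log2, glycerolipid genes 2 higher and 2 lower of 20 (7), and glycolysis 2 of 25 lower (2). Lipases had 2 of 11 higher (3), with dob at 1.51 ± 0.21 log2 (adjusted p = 0.46 with an estimated correlation), fatty acid oxidation 3 of 23 (3) and the unfolded protein response 4 of 19 (6), with adjusted p = 0.708 with an estimated correlation for each. Lipoproteins had 5 higher and 2 lower of 16 (8) and detoxification 5 and 3 of 23 (9), with catalase Cat at 2.06 ± 0.26 log2.

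Ribosomal proteins had 0 of 89 called, with a median of 0.116 and a mean of -0.055 log2, and proteasome genes and mitochondrial transcripts had 0. Of tissue markers, midgut had 2 of 15 lower (4), muscle 1 of 14 (1) and neurons 1 of 12 higher, while gonad had 0 of 22 with a median of -1.82 log2. Without the mixed library 15 of 22 gonad markers were lower (18 adjusted over the list alone) with a median of -3.11 log2, and fatty acid oxidation had 7 of 23 higher (7). The camera call for larval serum proteins held with an estimated correlation (0.0428), but not without the mixed library, where adjusted p = 0.114 with an estimated correlation. By fry larval serum proteins passed (adjusted p = 0.000174), as did nutrient, ecdysone response, lipoprotein, lipase and respiratory chain genes (0.0119 to 0.0396). The count was 1103 without per0 CT8 B, 1113 without CT4 A, 1115 without CT32 A, 1123 without CT28 A, 1136 without CT24 A, 1138 without CT4 B and 1165 without CT32 B, and 306 without both days at the CT8 phase.

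The genotypes were compared over all times. In per0 most respiratory chain, ribosomal protein, fatty acid synthesis and detoxification genes were called higher and 4 of 6 larval serum protein genes lower, although no list passed the camera test with an estimated correlation. By fry these 5 lists passed (adjusted p of 8.12e-06, 0.000362, 2e-06, 6.45e-07 and 0.000296). The P450 gene Cyp6a2, linked to insecticide metabolism, was higher by 5.90 ± 0.46 log2 (n = 18 libraries against 18), and the immune recognition gene PGRP-SD by 3.29 ± 0.36 log2. Zw was higher by 1.75 ± 0.19 and Pgd by 1.36 ± 0.15 log2. Eip93F, an ecdysone-induced transcription factor, measured -3.40 ± 0.41 log2.

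Of 12020 genes 5095 passed, 2327 higher and 2768 lower in per0. Without the mixed per0 CT28 B library 6432 of 12441 passed, 2547 higher and 3885 lower, and 5013 were called both times. With the filter of 10 CPM the balance turned, with 1887 higher and 1517 lower, and with a larval serum protein covariate 2626 genes passed. The largest changes were in genes nearly silent in 1 genotype, such as CG14567 at 9.91 ± 0.36 and lncRNA:CR44316 at 10.49 ± 0.52 log2 higher, and nAChRalpha7 at -6.92 ± 0.73 and Hs3st-A at -6.90 ± 0.70 log2. In the core clock 5 of 15 genes were higher and 7 lower (12 adjusted over the list alone). Pdp1 was higher by 1.51 ± 0.16 log2 (adjusted p = 3.91e-08) and cwo by 0.71 ± 0.08 log2, while Clk measured -3.62 ± 1.04, cyc -1.51 ± 0.35 and vri -1.11 ± 0.30 log2. Clk did not pass the count filter in the fits of per0 alone, so its value rests on low counts there. The tim transcript did not differ detectably (-0.05 ± 0.36 log2).

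Respiratory chain genes were higher in 60 and lower in 2 of 65 cases (62 adjusted over the list alone), with ND-13A at 0.89 ± 0.09 log2 (adjusted p = 0.5 with an estimated correlation). Ribosomal proteins were higher in 80 and lower in 3 of 90 (85, adjusted p = 0.667 with an estimated correlation), where the near-identical pair RpS14a and RpS14b is uncertain. Fatty acid synthesis had 12 of 16 higher and 0 lower (14, adjusted p = 0.42 with an estimated correlation), with FASN2 at 1.72 ± 0.24 log2, and glycerolipid genes 8 of 20 higher (8, adjusted p = 0.667 with an estimated correlation), with Agpat2 at 1.42 ± 0.18 log2. Glycolysis had 15 higher and 1 lower of 25 (17, adjusted p = 0.667 with an estimated correlation) and detoxification 13 and 2 of 23 (15, adjusted p = 0.42 with an estimated correlation). Mitochondrial transcripts had 12 of 18 higher (13, adjusted p = 0.667 with an estimated correlation), proteasome 17 of 31 (17, adjusted p = 0.882 with an estimated correlation) and ribosome biogenesis 9 higher and 1 lower of 18 (10, adjusted p = 0.766 with an estimated correlation). Fatty acid oxidation went both ways, 3 higher and 9 lower of 23 (16), with yip2 at -1.47 ± 0.14 and Echs1 at 1.10 ± 0.14 log2. Lipases had 2 higher and 3 lower of 12 (5), with dob at -1.45 ± 0.13 log2, and lipoproteins 4 and 4 of 16 (8).

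Larval serum proteins had 4 of 6 lower in per0 (4 adjusted over the list alone, adjusted p = 0.667 with an estimated correlation), with Lsp2 at -3.32 ± 0.96 log2, and the ecdysone response 1 higher and 7 lower of 17 (8). Nutrient genes had 1 higher and 3 lower of 18 (1), antimicrobial peptides 4 and 3 of 20 (7), the unfolded protein response 5 and 1 of 19 (5), heat shock 4 and 1 of 11 (5), and clock outputs 2 of 7 higher (2). Hemocyte markers were higher in 6 and lower in 1 of 12 (7), neuron and glia markers lower in 5 of 12 (5), cuticle markers higher in 4 of 15 (1) and Malpighian tubule markers higher in 2 of 5 (2). Midgut had 0 of 17 called, muscle 1 of 14, salivary gland 0 of 10, sex composition 0 of 5 and strain markers 0 of 3. Gonad markers were lower in 2 of 23 (1), and in 9 of 23 (6) without the mixed library. The median of heat shock genes lay near 0 and changed sign under other scalings.

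**Figure D4:**
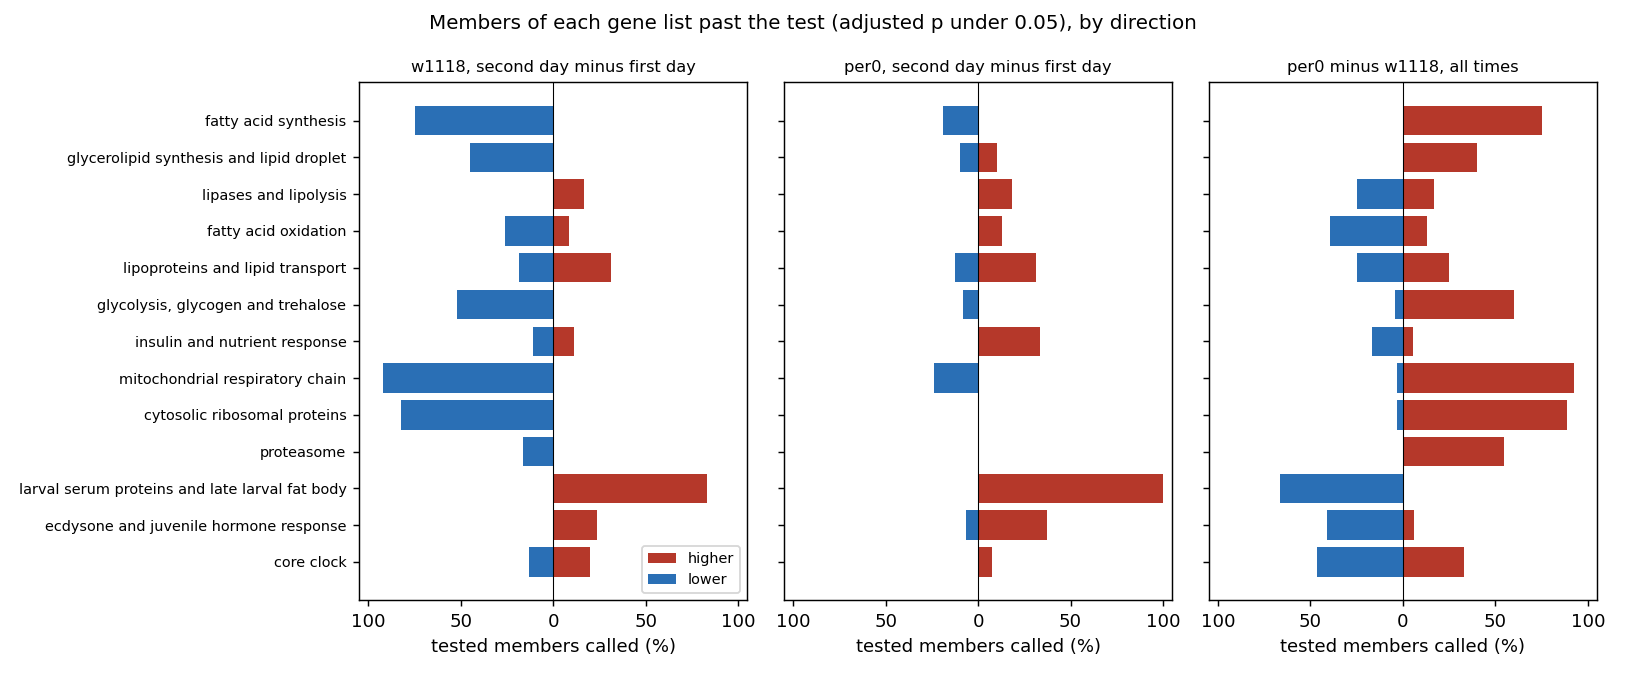
Percent of tested list members called higher and lower, for the second day against the first in w1118 and in per0 and for per0 against w1118, in 13 gene lists. In the genotype comparison 60 of 65 respiratory chain genes were higher in per0, and on the second day 60 of 65 were lower in w1118. The genotype panel used all 36 libraries and each second-day panel 12 of its genotype. The mixed library enters the per0 and genotype panels.

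The last comparison asked whether the second-day change differed between genotypes. The log2 rise of storage proteins was larger in per0, with Lsp2 at 8.26 log2 above the w1118 change (adjusted p = 0.0122). For Lsp1 genes per0 started from a lower share of counts, as given above. Acly, which fell in w1118, differed by 1.55 ± 0.34 log2 (adjusted p = 0.044), and CG4860 by 1.33 ± 0.28 log2 (adjusted p = 0.0384). Of 11815 genes 59 passed, 50 with a more positive change in per0 and 9 with a more negative one, and 1302 had an unadjusted p under 0.05. The count was 26 with a roX covariate, 20 with a gonad marker covariate, 106 with larval serum protein genes left out of the scaling, 171 with the filter of 10 CPM and 344 by DESeq2.

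Without the mixed per0 CT28 B library 186 of 12283 genes passed, 120 more positive and 66 more negative, and all 59 were among them. Larval serum proteins had 2 of 6 members called (5 adjusted over the list alone) and passed the camera test with an estimated correlation too (0.00554), also without the mixed library (0.0302). By fry they were the list that passed (adjusted p = 0.000806). Fatty acid synthesis had 1 of 16 (10, adjusted p = 0.198 with an estimated correlation). Without the mixed library 7 of 16 passed (11), with ACC at 1.85 ± 0.32, Acly at 1.70 ± 0.31 and Pgd at 1.07 ± 0.19 log2, and the camera test then held with an estimated correlation (0.0382). Larval serum proteins, and fatty acid synthesis without the mixed library, were the camera calls that held with an estimated correlation. Glycolysis had 0 of 25 (5, adjusted p = 0.244 with an estimated correlation), ribosomal proteins 0 of 90 (adjusted p = 0.31 with an estimated correlation) and the respiratory chain 0 of 65 (adjusted p = 0.436 with an estimated correlation). Gonad markers had 0 of 23 called, at a median of -3.9 log2. The count was 28 to 39 without single w1118 libraries of CT0 A, CT0 B, CT4 A, CT8 A, CT24 B, CT32 A or CT32 B or per0 libraries of CT0 A, CT8 A, CT8 B, CT24 A or CT32 A, 7 without the CT8 phase, 22 without CT0 and 737 without CT4, the phase that holds the mixed library. Leaving the larval serum protein genes out of the scaling shifted genes by a median of 0.27 log2.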

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

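The tests of the mixed library, of developmental age and of tissue carried along were chosen after the result was seen.

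The second-day change differed between genotypes in 59 genes by the interaction test, and those named here stood out for that reason. Lsp2 differed by 8.26 log2, with 4.14 in w1118 and 12.57 in per0. CG7763 differed by 7.19, the yolk protein gene Yp3 by 4.74, the carbonic anhydrase gene CARPB by 3.69, Lsp1gamma by 3.00, Kal1 by 2.84, CG3961 by 2.68, CG4630 by 2.56 and Kr by 2.13 log2. The ornithine decarboxylase gene Odc2 differed by 1.88 log2, with -2.09 in w1118 and 0.00657 in per0, Acly by 1.55 and CG4860 by 1.33 log2. In the other direction Fnta differed by -0.77, CG32795 by -0.90, Rgl by -1.31, CG3700 by -1.57, CG13315 by -1.92, CG4269 by -2.10, CG17260 by -2.32 and the caspase gene Decay by -2.37 log2. With genotypes exchanged at random within times, 4 of 100 splits gave at least 59 genes and the highest other gave 1530. Chance is not clearly excluded, since some splits called far more genes than the real one, which points to a structure of the samples. Of the 20 genes named here 15 lost their call under an alternative and 18 when a library or phase was left out. Without the mixed per0 CT28 B library the count was 186, with a roX covariate 26 and with a gonad covariate 20, so the sex of the pools may account for a part.

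The per0 CT28 B library stood between the genotypes. Genes higher in w1118 reached a median share of 0.52 of the way to w1118, with an upper quartile of 0.7, which argues against a whole library exchanged with w1118. Genes higher in per0, which an addition of w1118 material should lower, lay a median share of 0.57 toward w1118, above the 0.27 that was highest elsewhere in per0. This is consistent with RNA or larvae of w1118 mixed into the library. Whether this happened among larvae, RNA or libraries, or through crossed larvae, stays open, and no biological explanation was tested.

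The genotype difference, 5095 genes, was matched by 1 of 100 splits, the real one, and the highest other called 55. Chance in the grouping of single libraries is therefore excluded. Of 54 midgut, muscle and gonad markers 3 were called, but 10 of 55 without the mixed library, and with a gonad covariate 70.4% of the genes stayed called, so tissue carried along may account for a part. Of the genes called both here and for the second day in w1118, 95.4% had opposite signs (1151 of 1206, r = -0.74 across all genes), as a younger stage of the per0 larvae would give, but both comparisons use the same w1118 libraries and no value under no change was computed. With per0 as the day comparison 819 of 932 did (r = -0.04), but 804 of 1336 (r = 0.3) without the mixed library, so age cannot be told apart from other sources. With a larval serum protein covariate, a measure of stage, 2626 genes were called. Strain background and the loss of per are untested.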

How the results depend on the processing

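The letter, gonad and larval serum protein settings, and the omission of time points from the any-time, day and genotype tests, were chosen after the data were seen; the others were planned. No paired analysis was possible because no label ties the column letters to the replicate numbers, where paired means blocked by replicate number. With the letter itself as a covariate all 14 counts stayed within 1.5 times. Where a count moved, the cause was not tested unless fewer libraries were used.

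For 24 h in w1118 (72 calls) there were 112 with DESeq2 size factors, 162 with the 10 CPM filter, 40 with roX, 119 with gonad markers, 183 with linear time, 53 for the 24 h pair alone, 0 for a 20 h and 31 for a 28 h pair alone, 156 by limma on the authors' normalized values and 406 by DESeq2. For 12 h (0) there were 2 with DESeq2 size factors, 6 with the filter, 1 for a 10 h pair alone, 18 by limma on normalized values and 254 by DESeq2, and for 8 h (0) 7 by DESeq2. For any time (1426) there were 2185 with the filter, 884 with roX, 765 with gonad markers and 5473 by DESeq2, and for the second day (1715) 1013 with gonad markers.

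For 24 h in per0 (0) there were 2 for the 24 h pair alone and 93 by DESeq2. For 12 h (0) there were 1 with gonad markers, 1 for the 12 h pair alone, 1 for a 10 h and 11 for a 16 h pair alone and 313 by DESeq2, for 8 h (0) 40 by DESeq2, and for any time (1061) 699 by voom and 4096 by DESeq2. The genotype count (5095) was 2626 with the larval serum protein covariate, under which Lsp1alpha and Lsp1gamma, lower in per0 otherwise, reversed to 0.47 and 0.45 log2, since that covariate holds those genes themselves. The 24 h difference (0) was 10 by DESeq2. The 12 h difference (0) was 1 with the filter, 1 with larval serum protein genes left out and 4 by DESeq2. The day difference (59) was 171 with the filter, 26 with roX, 20 with gonad markers, 106 with larval serum protein genes left out and 344 by DESeq2.

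Leaving out each library or time gave, in w1118, 11 to 137 for 24 h, 0 to 448 for 12 h, 0 to 1 for 8 h, 841 to 2089 for any time and 557 to 1766 for the second day. In per0 it gave 0 to 424 for 12 h, 396 to 1588 for any time and 306 to 2615 for the second day. It gave 3977 to 6432 for genotype, 0 to 1 for the 12 h difference and 7 to 737 for the day difference. For 8 h and for the 12 h difference only single libraries were left out, and for the day tests single libraries or clock phases.

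Of called genes followed by name, those that lost their call under an alternative, and with a library or time left out, were 6 and 1 of 6 for 24 h in w1118, 2 and 4 of 26 and 4 and 7 of 19 for any time in w1118 and per0, 4 and 16 of 28 and 4 and 6 of 17 for the second day, 9 and 5 of 34 for genotype and 15 and 18 of 20 for the day difference.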

Other observations

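The test of the 24 h genes in per0 and under a gonad covariate, the ribosome biogenesis test without CT0, the orders for 24 h in w1118 at an unadjusted p and the count of letter assignments were chosen after the result was seen.

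Gonad RNA varied between pools, which the labels call mixed in sex. In per0 the male-expressed roX1 measured 63.1 to 341 CPM in 13 libraries but 0.468 to 2.15 CPM in CT20 A, CT20 B, CT24 B, CT28 A and CT32 A, where betaTub85D was at most 0.0866 CPM, so those pools held few or no males by these markers. The testis tubulin gene betaTub85D lay at or under 0.105 CPM in 6 w1118 libraries and reached 281 CPM in w1118 CT24 B. In w1118 the roX genes, expressed in males, followed the gonad marker profile across 18 libraries with r = 0.81 and rho = 0.8 (permutation p = 3e-05 and 0.00011, adjusted 4.8e-05 and 0.00015 over 4 relations with both measures, r = 0.79 without the 2 farthest libraries). In per0 these were r = 0.55 and rho = 0.5 (permutation p = 0.017 and 0.037, adjusted 0.02 and 0.037, r = 0.47 without the 2 farthest). The gonad profile followed the number of genes detected, with r = 0.94 and rho = 0.88 in w1118 (permutation p = 1e-05 for each, the smallest these resamples can give, adjusted 2.7e-05, r = 0.92 without the 2 farthest) and r = 0.84 and rho = 0.89 in per0 (permutation p = 3e-05 and 1e-05, adjusted 4.8e-05 and 2.7e-05, r = 0.87 without the 2 farthest). The per0 value includes the mixed CT28 B library, which had the most genes detected of per0, 12955. Midgut markers summed to 1.21 to 15100 CPM in w1118 and 1.02 to 25000 CPM in per0.

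Much of the second-day change was shared. Of 10228 genes tested in both genotypes 279 rose in both, with 46 expected if independent, 374 fell in both, with 90 expected, and 9 were called in opposite directions, with 147 expected. Without the mixed library, of 10348 genes, these were 278 (56 expected), 328 (159) and 28 (201).

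The source of the 72 genes called for 24 h in w1118 is open. Of 100 orders of the time points 23 gave as many calls and the highest other gave 4812, so chance is not excluded, and the orders with many calls point to a structure of the samples. The median ratio of peak-to-trough with the gonad covariate to that without was 1, which argues against gonad content as the source. The mean profile of these genes in per0, which need not be independent of the selection in w1118, gave an exact p = 0.0231 for 24 h, peaking at CT14.1, and 0.0266 for 12 h, and exact p-values of 0.0419 and 0.0433 without the mixed library. Neither pair of p-values was adjusted, and z-scores drop the size of the change, which for Thor measured 4.95 log2 in w1118 and 0.71 in per0 (adjusted p for the difference 0.548). The Thor value in per0 includes the mixed library. A cycle that needs per, a cycle without it and an event shared by the sampling of both genotypes therefore cannot be told apart.

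Without CT0, 448 genes passed for 12 h in w1118 and ribosome biogenesis had 17 of 18 called, but 17 of 100 orders of the 8 other times gave as many calls (highest other 1955) and the list's profile gave an exact permutation adjusted p of 0.429, so a 12 h cycle there cannot be told apart from chance with 8 times. Without CT8, 424 passed in per0, and 13 of 100 orders gave as many (highest other 1517). Of 10432 genes tested in both, 36 passed both times, with 17.5 expected, but the phases of the calls differed. In w1118 370 of the 448 peaked near hour 3 to 4 of the 12 h cycle and 22 near hour 8 to 9, against 9 and 235 of the 424 in per0, where 0 of 18 ribosome biogenesis genes were called.

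Chance was not excluded for genes at an unadjusted p under 0.05 in the 24 h and 12 h tests, and 8 h alternation had no such test. For 24 h in w1118, 50 of 100 orders gave at least 1114 genes (highest other 5677), and for 12 h 49 of 100 orders gave at least 992 genes (highest other 5105). For per0 54 gave at least 1148 for 24 h (highest other 3441) and 62 gave at least as many as the real order for 12 h, 10.2% of genes (highest other 3572). For the differences between genotypes 26 splits gave at least 734 genes for 24 h (highest other 3959) and 9 at least 1730 for 12 h (highest other 3864). For the second day, 2 of 100 splits reached 1715 in w1118 (highest other 2683) and 1 reached 1752 in per0 (highest other 302). Chance in the grouping of single libraries is excluded for per0 at that share. For w1118 it is not clearly excluded, since another split called more genes than the real one. Splits separated the duplicates of a time, so chance differences between collections are not excluded. The w1118 split with 2683 calls grouped libraries with mean gonad profiles of -0.5 and 1.12, a structure of the samples.

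In per0, 227 genes had the same sign of the difference between column B and column A at all 9 times, 186 of them higher in B. Of 256 assignments of the letters 1 gave as many, the real one (highest other 152). In w1118 there were 28 such genes, and 74 of 256 assignments gave as many (highest other 222). Midgut markers in per0 were higher in B at all 9 times, by a median of 7.46 log2 at CT4 and of 0.16 at CT32. Midgut tissue as the sole source is argued against by CT32, where genes chosen from the other 8 pairs still differed in their own direction by a median of 0.42 log2. Exon length was taken as all annotated exons of a gene combined, which is not the length of a transcript. Its median was 2.15 times that of other genes for genes higher in B, and 0.72 times for the 41 lower in B. Without the CT28 pair 272 genes had the same sign in 8 pairs, and 1 of 128 assignments gave as many.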
